A study of Mus musculus with 77 samples.

How the data were processed

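RNA of livers from male B6C3F1 mice was measured on 1-colour Illumina bead arrays after 7 days of exposure, in 77 samples of 18 groups. Per the labels, RNA was extracted with Trizol and RNeasy columns with a DNase I step, checked on a Bioanalyser and labelled as biotin cRNA with an Ambion MessageAmp kit. The compounds, each at 4 doses, were phenobarbital (PB) and 3 phthalate esters: DEHP with 2-ethylhexyl chains, DNOP with linear octyl chains, and BBP with a benzyl and a butyl group. The labels give the doses in ppm without naming the medium. There were 10 phthalate controls, 4 phenobarbital controls and 4 samples in each dose group, except 3 at 10000 ppm DNOP.

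The deposited signal table holds, per the file headers, an average bead signal per gene and array. These values are an intensity on a linear scale that the authors had neither normalized between arrays nor corrected for background, since the array medians differ and no value lies near 0. The same deposited table holds, per the file headers, a detection p-value (unit: p-value) of each signal against the negative control beads of its array. A deposited matrix of the series holds an intensity that the authors had normalized by a method they do not state. Its sorted values differ between arrays by a median of 0.1123%, and its Spearman correlation with the signal of the same array was at least 0.9976. The signal table has 1 value for each of 18138 array IDs and the matrix has 18132 of them. Of the IDs, 14307 are symbols of the mouse RefSeq gene table, 2703 were matched through a synonym, and 1128 had no match and kept their array ID. The array gives 1 value per gene without a position, so no genome coordinates belong to these values.

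Depth on these arrays is the signal over background, which limits dim genes, and the number of arrays per group limits the precision stated. The percent of genes detected (detection p under 0.05) ran from 36.88% to 46.64% with a median of 44.29%. The mean signal ran from 132.2 to 519.5 with a median of 359.8, and the background mean from 77.37 to 123.2 with a median of 101.5.

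The signal was corrected with the normal-exponential model of limma 3.58.1 in R 4.3.3, given an offset of 16, turned to log2 and quantile normalized. The offset and the background set the folds of genes that are dim in 1 group, so for such genes the range over 5 scalings is given (as in the fit of all samples, no background correction, each array centred on its median, neqc's background and the deposited matrix), a choice made after seeing the data. The background mean and SD of each array came from the detection p-values that lie on the grid of the negative controls (78.13% of them, 798 steps), fitted in 50 bins. The plan made before the data were examined named the function neqc, which uses all detection p-values. That function inferred a background SD of 120 (median over arrays) against 6.037 from the values on the grid, and the cause of the difference was not tested. The choice of the grid was made after seeing these parameters and before comparing any group, and the values of neqc itself were run as an alternative. On simulated arrays with a background mean of 100 and an SD of 6, the grid gave 100 and 5.99. A gene was tested when its detection p was under 0.05 on at least 3 arrays, which left 11324 genes, 10671 of them with a reference symbol.

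All 77 samples entered 1 limma fit of 18 group means, with 59 residual degrees of freedom and a prior of 3.19. The labels give each sample a number with a letter (32A, for example) and do not say what the number stands for. The 62 numbers were a random block with a correlation of 0.0992. The labels do not say which samples are separate animals, so the p-values measure the spread between samples. Genes past a Benjamini-Hochberg adjusted p of 0.05 within a comparison were called changed, with no fold threshold. The comparisons were each dose against the controls of its part of the study, DEHP against BBP at the 3 doses both were given, and the PB controls against the phthalate controls. Every interval is a 95% confidence interval.

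Named genes followed a rule fixed before the data were examined. They were a panel (Cyp4a10, Cyp4a14, Ehhadh, Acot1, Pdk4, Vnn1, Fgf21, Cyp2b10, Cyp2c55, Cyp3a11, Gstm3, Mki67, Top2a, Ccnb1, Cdk1, Ccnd1 and Mcm5), the 5 largest rises and the 5 largest falls among called genes whose groups of samples did not overlap, and up to 4 called members of each list with the largest change. Cyp4a10 and Mki67 have no match on the array, and Vnn1 was not detected. A further gene of the panel is not reported here, and it still enters the counts and lists of all genes.

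The gene lists fixed before the data were examined hold 541 genes, cell type markers aside. They cover targets of the receptors PPARA and CAR, the cell cycle, cholesterol synthesis, fatty acid synthesis, bile acids, NRF2 and glutathione, AHR targets, the acute phase, coagulation and complement, amino acids and the urea cycle, gluconeogenesis and fasting, p53 targets, unfolded protein and stress responses, male-biased and female-biased liver genes and the circadian clock. Lists of cell type markers cover Kupffer cells, lymphocytes, neutrophils, endothelial cells, stellate cells, cholangiocytes, pancreatic acinar cells, adipocytes and red cells. Lists were tested with camera of limma, two-sided, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over all lists of a comparison. Members were counted after adjustment over all genes and over the list alone. List means per sample of the PPARA, CAR and cell cycle lists were compared with two-sided exact permutation tests in a family of 60, adjusted by Benjamini-Hochberg. Overlaps of called genes were compared with Fisher's exact test, one-sided for more shared genes. For phthalates, which share controls, overlaps and correlations were also computed after splitting the controls by number, and correlations in 20 simulations without shared effects.

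On simulated data with real group sizes, a 2-fold change was recovered for 94% of genes at 6000 ppm DEHP, 94% at the lowest DNOP dose, 83.6% at 1500 ppm BBP and 82.1% at 600 ppm PB. A simulated shift of 1 list by 0.5 (log2) was called and 0 of the 25 other lists were, with camera of limma. The simulated genes were drawn independently, so this does not bear on false calls in lists of correlated genes.

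Alternatives chosen before the data were examined were no background correction, centring each array on its median in place of quantile normalization, the deposited matrix, no filter, a strict filter (detection p under 0.01 on every array of at least 1 group, 6863 genes), no block, samples of 1 number averaged, a replicate block, only the groups of the same compound, a trended robust prior, and leaving out each sample in turn. Those chosen after seeing the data were neqc's own background, the fit without the phthalate controls numbered 32, without the 2 dimmest PB controls, without 4 arrays of low quality weight, with array quality weights, and PB doses against the phthalate controls. Centring each array on its median moved the median of all genes by −0.132 at 3000 ppm DEHP, −0.128 at 6000 ppm DEHP, −0.118 at 5000 ppm DNOP, −0.129 at 6000 ppm BBP, −0.126 between DEHP and BBP at 3000 ppm, and −0.127, −0.182, −0.14 and −0.185 at the rising PB doses (log2). In the quantile normalized values these medians stayed within 0.02 of 0. No slide was given in the labels or files and each gene had 1 value, so a slide block and another choice of probe were not run. Figures were drawn with matplotlib 3.10.9 and tables with pandas 2.3.3 in Python 3.11.15.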

Results

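Liver RNA of male B6C3F1 mice was profiled after 7 days of exposure to graded doses of 3 phthalate esters and of phenobarbital. The design asks at which dose each compound begins to change hepatic gene expression and which genes the compounds share. DEHP and DNOP are isomers that carry branched 2-ethylhexyl and linear octyl esters, BBP carries a butyl and a benzyl ester, and phenobarbital is a barbiturate that activates the nuclear receptor CAR. DEHP was given at 750, 1500, 3000 and 6000 ppm and BBP at 1500, 3000, 6000 and 12000 ppm. DNOP was given at a dose labelled 1.25K, the lowest, and at 2500, 5000 and 10000 ppm, and phenobarbital at 75, 150, 300 and 600 ppm. There were 10 phthalate controls, 4 phenobarbital controls, 3 samples at 10000 ppm DNOP and 4 in every other group, and the number of arrays limits the precision. A median of 44.29% of genes was detected per array, and the dimmest array was phenobarbital control replicate 1 with 36.88%.

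The phthalate controls were not alike. Replicates 1 to 3, which share the number 32 in their labels, had a mean of 9.07 ± 0.122 (SD, n = 3, log2 intensity) over target genes of PPARA, the nuclear receptor that turns on fatty acid oxidation. The other phthalate controls had 8.17 ± 0.165 (SD, n = 7). Every phthalate comparison was therefore also run without these 3 controls, a choice made after seeing the data. Since they were picked for high PPARA targets, leaving them out raises the difference of this list from the controls. PPARA calls gained in that way are no separate support.

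DEHP raised genes of fatty acid oxidation at its lowest dose and most of the PPARA list at 1500 ppm. At 6000 ppm the acyl-CoA thioesterase gene Acot3 rose 30.3-fold (log2 change 4.92, SE 0.441, limma adjusted p = 1.85e-13). It was detected in 3 of 10 controls, and the fold ran from 9.34 to 31.1 over the scalings. The fatty acid hydroxylase genes Cyp4a14 and Cyp4a31 rose 29.6-fold and 24.7-fold, and Acot1 21.6-fold. Ehhadh, a peroxisomal oxidation enzyme, rose 23.2-fold, with log2 intensities of 11.9 ± 0.667 (SD, n = 4) against 7.37 ± 1.07 (SD, n = 10). Cyp4a14 was already 26.8-fold higher at 750 ppm (adjusted p = 0.000277) and between 29.6 and 35.9-fold higher at the other doses. Leaving out the controls numbered 32 put Cyp4a14 at 68.8, 92.1, 86.7 and 76-fold at the 4 doses. At 6000 ppm it put Acot1 at 42.3-fold and Ehhadh at 34.7-fold. Pdk4, which restrains pyruvate use, rose 4.85-fold at 6000 ppm (adjusted p = 0.000256; 7.35-fold without those controls), and the hormone gene Fgf21 stood at 0.50 (adjusted p = 0.63; 1.15 without them, adjusted p = 0.101).

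Of 55 tested PPARA targets, 18, 36, 44 and 35 rose at the 4 DEHP doses and 0 fell, where limma gave 1467, 1896, 2359 and 2348 of all genes at an unadjusted p under 0.05. Adjusted over the list alone, 28, 40, 48 and 43 rose. List medians were 0.40, 0.90, 1.12 and 1.05 (camera adjusted p = 9.50e-23, 1.45e-51, 3.03e-62 and 3.91e-49), and these calls held with an estimated correlation. The list mean per sample was 0.67 above the controls at 750 ppm (interval 0.384 to 0.961; two-sided exact permutation p = 0.024, adjusted 0.0553). It was 1.15, 1.45 and 1.33 above them at the higher doses (exact p = 0.000999 for each, the smallest possible, adjusted 0.005). The permutation tests and intervals take controls that share a number as independent. Of these targets, 18 passed from 750 ppm upward, 15 from 1500 ppm and 2 from 3000 ppm.

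Over all 11324 genes, DEHP changed 218 genes at 750 ppm (129 higher, 89 lower) and 518 at 1500 ppm (287 and 231). It changed 957 at 3000 ppm (504 and 453) and 1064 at 6000 ppm (594 and 470). Of the calls at the 3 lower doses, 141 of 218, 368 of 518 and 611 of 957 were called in the same direction at 6000 ppm. The count at 750 ppm was 78 and 100 without replicates 2 and 4, 333 without control replicate 1 and 332 without the controls numbered 32; at 1500 ppm it was 321 without replicate 1, at 3000 ppm 597 and 602 without replicates 1 and 2, and at 6000 ppm 651 and 686 without replicates 2 and 3. Centring each array on its median gave 81 and 267 genes at 750 and 1500 ppm, averaging the samples of 1 number gave 108, 317 and 617 at the 3 lower doses, and array quality weights gave 1364 at 1500 and 1966 at 3000 ppm.

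**Figure D1:**
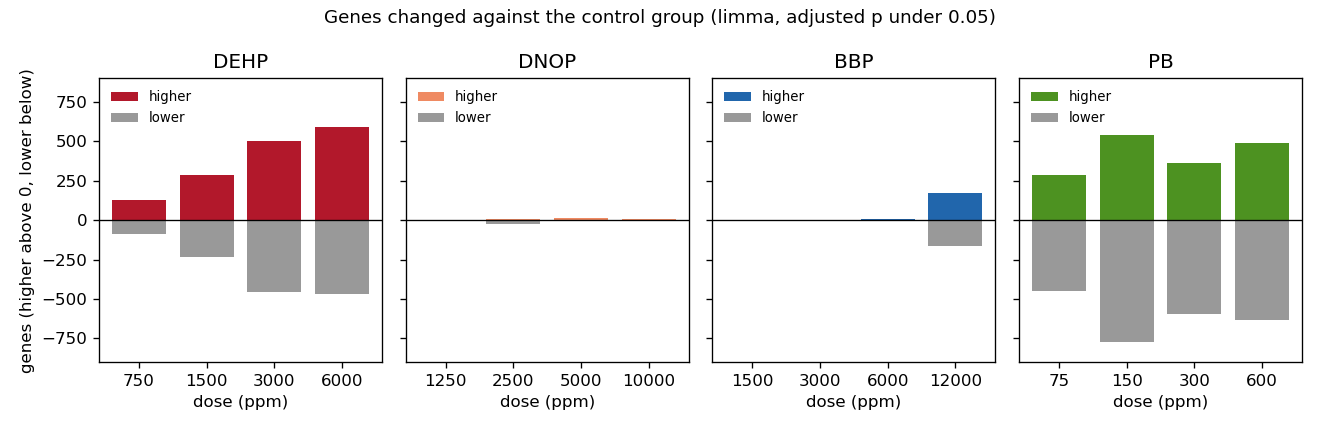
Number of genes past the adjusted p of 0.05 at each dose in ppm of each compound against its controls, with genes higher above 0 and genes lower below 0. DEHP changed 218 to 1064 genes, DNOP at most 27, BBP 9 at 6000 ppm and 334 at 12000 ppm, and phenobarbital 733 to 1311.

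DEHP also raised targets of CAR, the receptor that turns on drug metabolism. At 6000 ppm Cyp3a11 rose 11.1-fold (adjusted p = 1.33e-07; log2 change 3.48, and 4.18 without replicate 1), the export pump gene Abcc3 6.29-fold and Cyp2b9 6.21-fold. Cyp2b10 rose 3.9-fold (log2 change 1.96, SE 0.231, adjusted p = 1.25e-09) and Cyp2c55 2.69-fold, while the glutathione transferase gene Gstm3 stood at 0.00152 (adjusted p = 0.998). Of 39 tested CAR targets, 4, 7, 16 and 13 rose at the 4 doses and none fell. Adjusted over the list alone, 5, 11, 20 and 15 rose and 1 fell, at 3000 ppm. List medians were 0.10, 0.48, 0.57 and 0.39 (camera adjusted p = 0.0169, 5.91e-08, 3.51e-11 and 1.17e-08). The call at 750 ppm was lost (adjusted p = 0.415 with an estimated correlation) and the other 3 held. Means of the list were 0.23, 0.50, 0.71 and 0.63 above the controls, each with a two-sided exact permutation p = 0.000999, the smallest possible (adjusted 0.005). Without the controls numbered 32, the median at 1500 ppm was 0.45 (camera adjusted p = 3.97e-07, lost with adjusted p = 0.051 with an estimated correlation). Cyp2b9 was detected in none of the 10 controls and Cyp2b10 in 1, and their folds ran from 2.19 to 6.21 and from 1.25 to 3.9 over the scalings. The calls of Cyp2b10 and Cyp2c55 ended with the background of neqc, where the log2 changes were 0.33 and 0.35, and that of Cyp2c55 also without replicate 2 (1.01).

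Cell cycle genes rose at 6000 ppm DEHP. There 21 of 47 tested members were higher and none lower (27 and 2 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 8.18e-12, held with adjusted p = 0.0233 with an estimated correlation). The median was 0.39 when the controls numbered 32 were left out (camera adjusted p = 5.01e-10, lost with adjusted p = 0.0504 with an estimated correlation). The mitotic genes Prc1 (1.43), Spc25 (1.34) and Cdc20 (1.19) and the G1 cyclin gene Ccnd1 (1.33, SE 0.323, adjusted p = 0.00294) rose most. Top2a, Ccnb1, Cdk1 and the replication helicase gene Mcm5 rose by 0.48, 0.56, 0.37 and 0.71. The first 3 were detected in none of the 10 controls and Cdc20 in 5, and over the scalings they ran from 0.05 to 0.48, 0.08 to 0.56, 0.04 to 0.37 and 0.21 to 1.19. At the 3 lower doses the list medians were 0.08, 0.22 and 0.13, and the last turned to −0.07 with each array centred on its median. Their camera calls (adjusted p = 0.00736, 1.27e-09 and 0.00682) were lost, with adjusted p = 0.473, 0.0516 and 0.425 with an estimated correlation. Means of the list were 0.15, 0.29 and 0.15 above the controls there (two-sided exact permutation p = 0.002, 0.000999 and 0.002; adjusted 0.00799, 0.005 and 0.00799), and 0.40 above them at 6000 ppm (adjusted 0.005). There 0, 4 and 2 members rose (limma unadjusted p under 0.05 for 1467, 1896 and 2359 of all genes). Replicate 3 of 6000 ppm stood apart with a list mean 0.852 above the controls, against 0.193 to 0.284 in the other 3 samples. Without it 8 of the 21 genes were called, and the calls of Top2a (0.34), Ccnb1 (0.10), Cdk1 (0.13) and Mcm5 (0.66) ended, the last also without replicate 2 (0.72). The calls of Top2a (0.22), Ccnb1 (0.30) and Cdk1 (0.12) also ended with each array centred on its median, and that of Mcm5 (0.13) with the background of neqc.

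Genes of secreted coagulation and complement proteins fell with DEHP. Of 32 tested members 0, 14, 20 and 21 fell at the 4 doses and none rose (limma unadjusted p under 0.05 for 1467 of all genes at 750 ppm). Adjusted over the list alone, 9, 21, 22 and 23 fell, and 1 rose at 750 and 1 at 6000 ppm. The medians were −0.24, −0.40, −0.48 and −0.51 (camera adjusted p = 1.44e-07, 4.89e-15, 3.52e-19 and 1.86e-19), and these calls held with an estimated correlation. At 6000 ppm the complement genes C9 (−1.23), C8b (−1.20) and C8a (−1.19) and the clotting factor gene F11 (−0.97) fell most. The largest fall among genes whose groups did not overlap was that of Serpina12, the adipokine vaspin (−4.07, SE 0.287), with 7.45 ± 1.81 (SD, n = 4) against 11.5 ± 0.173 (SD, n = 10). In that set it was followed by the apolipoprotein gene Apoa4 (−2.31), the dynein chain gene Dnaic1 (−2.27), Lrtm1 (−2.24) and Serpina4-ps1 (−2.11).

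Sex-biased genes moved apart at 6000 ppm DEHP. Of 11 tested female-biased genes 8 rose and none fell, over all genes and adjusted over the list alone, with a median of 1.15 (camera adjusted p = 4.77e-10, held with an estimated correlation). Of these 11, 6 stand in another list, such as Acot3, Cyp4a14, Lpl and Cyp2b9. Of 19 male-biased genes 2 rose and 7 fell (2 and 10 adjusted over the list alone), with a median of −0.33 (adjusted p = 9.06e-06, held). Among them fell Selenbp2 (−1.34), the steroid dehydrogenase gene Hsd3b5 (−1.21) and the growth factor receptor gene Egfr (−0.99).

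Amino acid genes fell and p53 targets rose at 6000 ppm DEHP. Of 38 amino acid and urea cycle genes 1 rose and 7 fell, over all genes and adjusted over the list alone (list median −0.22, camera adjusted p = 0.000368, held with an estimated correlation). The median was −0.18 without the controls numbered 32 (camera adjusted p = 0.00364, lost with adjusted p = 0.0728 with an estimated correlation). Bhmt, which remethylates homocysteine, fell by 2.50, the proline dehydrogenase gene Prodh by 0.98, Hal by 0.83 and Gls2 by 0.81. The p53 targets Fas (0.77), Bbc3 (0.62) and Ccng1 (0.44) rose among 16 (list median 0.22, adjusted p = 0.0218, held). Leaving out the controls numbered 32 left 1 of the 16 called, with a larger median of 0.27 (camera adjusted p = 0.0413, lost with adjusted p = 0.0504 with an estimated correlation).

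The calls of 3 further lists at 6000 ppm DEHP were lost with an estimated correlation. Of 30 acute phase genes 1 rose and 9 fell (1 and 12 adjusted over the list alone), such as Serpina3m (−1.35), Saa4 (−1.31) and the fibrinogen gene Fgb (−1.28). The list median was −0.63 (camera adjusted p = 9.06e-06, lost with adjusted p = 0.274 with an estimated correlation). Of 21 cholesterol synthesis genes 4 rose (6 adjusted over the list alone), Cyp51 by 1.33, Nsdhl by 1.25, Acat2 by 0.95 and Hsd17b7 by 0.67. Their median was 0.41 (adjusted p = 0.000725, lost with adjusted p = 0.399 with an estimated correlation). The controls numbered 32 were low in this list, and without them 1 rose and the median was 0.15. The red cell marker list had a median of −0.64 (adjusted p = 0.0341, lost with adjusted p = 0.287 with an estimated correlation), with 1 of 7 members past the test, the heme synthesis gene Alas2 (−0.87).

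BBP had no gene past the test at 1500 and 3000 ppm and raised targets of PPARA at 6000 and 12000 ppm. At 12000 ppm Cyp4a14 rose 35.6-fold (log2 change 5.15, SE 0.797, limma adjusted p = 7.74e-06), Ehhadh 20.1-fold and Acot1 17-fold. Cyp4a31 rose 14.2-fold and Acot3 8.67-fold (2.71 to 8.73 over the scalings). With the controls numbered 32 left out, Cyp4a14, Ehhadh and Acot1 were 91.3, 30 and 33.3-fold higher. Fgf21 stood at 0.42 (adjusted p = 0.735; 1.07 without those controls, adjusted p = 0.216) and Pdk4 at 0.94 (adjusted p = 0.321). The change of Pdk4 passed without those controls (1.54, adjusted p = 0.0267) and with array quality weights (1.31, adjusted p = 0.038). At 6000 ppm 6 genes rose, among them the PPARA targets Cyp4a14 (15.4-fold, adjusted p = 0.0166; 39.6-fold without those controls), Ehhadh (5.2-fold, adjusted p = 0.00998), Retsat and Acadvl.

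Of the 55 PPARA targets 0, 0, 4 and 32 rose at the 4 BBP doses, where limma gave 399, 436, 989 and 1650 of all genes at an unadjusted p under 0.05. Adjusted over the list alone, 0, 0, 13 and 39 rose. The list medians were 0.01, 0.09, 0.18 and 0.81. The camera adjusted p was 0.732 at 1500 ppm and 0.00679 at 3000 ppm, the latter lost with adjusted p = 0.819 with an estimated correlation. It was 6.64e-10 at 6000 ppm, lost with adjusted p = 0.188 with an estimated correlation, and 4.06e-50 at 12000 ppm, which held. The list mean was 1.05 above the controls at 12000 ppm (interval 0.758 to 1.34; two-sided exact permutation p = 0.000999, the smallest possible; adjusted 0.005). It was 0.36 above them at 6000 ppm (interval 0.0754 to 0.652; exact p = 0.134). Without the controls numbered 32, 1, 2, 11 and 39 targets rose, and the calls at 3000 and 6000 ppm had adjusted p = 0.0277 and 0.00029 with an estimated correlation. These controls were left out for their high PPARA targets, so calls gained without them are no separate support.

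CAR targets and female-biased genes also rose at 12000 ppm BBP. Of 39 CAR targets 5 rose and none fell (8 rose adjusted over the list alone), with a median of 0.32 (camera adjusted p = 3.44e-08, held with an estimated correlation). Per sample the list mean was 0.46 above the controls (two-sided exact permutation p = 0.000999, adjusted 0.005). Abcc3 rose by 1.96, Cyp2b10 by 1.85 (3.61-fold, adjusted p = 6.24e-08), Aldh1a7 by 1.15 and Gstt3 by 1.0, while Cyp3a11 stood at 1.53 (adjusted p = 0.0665). The change of Cyp3a11 passed in 6 alternatives, with no block (1.54), a replicate block (1.54), control replicate 1 or 4 left out (1.64 and 1.66), the low-weight arrays left out (1.52) and array quality weights (1.56). Their adjusted p ran from 0.00339 to 0.0498. The call of Cyp2b10 ended with the background of neqc (0.32). Of 11 female-biased genes 5 rose (7 adjusted over the list alone; median 0.94, adjusted p = 3.85e-09, held). Of 47 cell cycle genes Spc25 alone rose, by 1.15, and the list median of 0.09 turned to −0.03 with each array centred on its median (adjusted p = 0.0012, lost with adjusted p = 0.335 with an estimated correlation). The cell cycle mean was 0.15 above the controls at that dose (two-sided exact permutation p = 0.002, adjusted 0.00799). It was 0.10 above them at 3000 and at 6000 ppm (exact p = 0.012, adjusted 0.04 for each), where the list median was 0.06 and 0.08, the latter turned to −0.24 with that centring.

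Coagulation and complement genes fell at 12000 ppm BBP, 12 of 32 (20 adjusted over the list alone), such as C8b (−1.02), C2 (−0.94) and C9 (−0.93). Their median was −0.35 (camera adjusted p = 2.46e-16, held with an estimated correlation). Of 30 acute phase genes 4 fell (14 adjusted over the list alone), such as Serpina3n (−1.20), with a median of −0.64 (adjusted p = 5.46e-08, lost with adjusted p = 0.149 with an estimated correlation). Of 19 male-biased genes 1 rose and 5 fell (3 and 6 adjusted over the list alone), with a median of −0.22 (adjusted p = 0.00496, lost with adjusted p = 0.143 with an estimated correlation). Among 23 fatty acid synthesis genes 3 rose and 1 fell, with Me1 at 2.36 and Fads2 at 1.34 (10 and 1 adjusted over the list alone). Among 21 cholesterol synthesis genes 3 rose (7 adjusted over the list alone), with Acat2 at 0.95. The medians of these lipid lists were 0.43 and 0.71 (adjusted p = 5.36e-06 and 7.42e-09), both lost with adjusted p = 0.143 with an estimated correlation. They rest in part on the controls numbered 32, without which the medians were 0.20 and 0.31. The largest falls among called genes whose groups did not overlap were those of Moxd1 (−2.91), Dnaic1 (−2.63), the ribonuclease gene Rnase2a (−2.39), the nicotinamide methyltransferase gene Nnmt (−2.02) and Fam25c (−1.30).

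Over all genes BBP changed 0, 0, 9 (6 higher, 3 lower) and 334 (170 and 164), where limma gave 399, 436, 989 and 1650 at an unadjusted p under 0.05. Other called genes at 6000 ppm included Abcc3 and Cyp4a12b, higher, and Chd4 and Ptms, lower, the last 3 named after their values were seen. Of the 9, 6 were called in the same direction at 12000 ppm. The count of 9 was 1, 3, 3 and 2 without replicates 1 to 4 of 6000 ppm and 29 and 15 without control replicates 1 and 3, the count of 334 was 150 and 187 without replicates 1 and 2 of 12000 ppm, and 1 gene passed at 3000 ppm without control replicate 1. The 4 counts were 1, 6, 28 and 444 without the controls numbered 32, array quality weights gave 108 and 928 at 6000 and 12000 ppm, averaging samples of 1 number gave 3 and 185, and centring each array gave 165 at 12000 ppm.

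**Figure D2:**
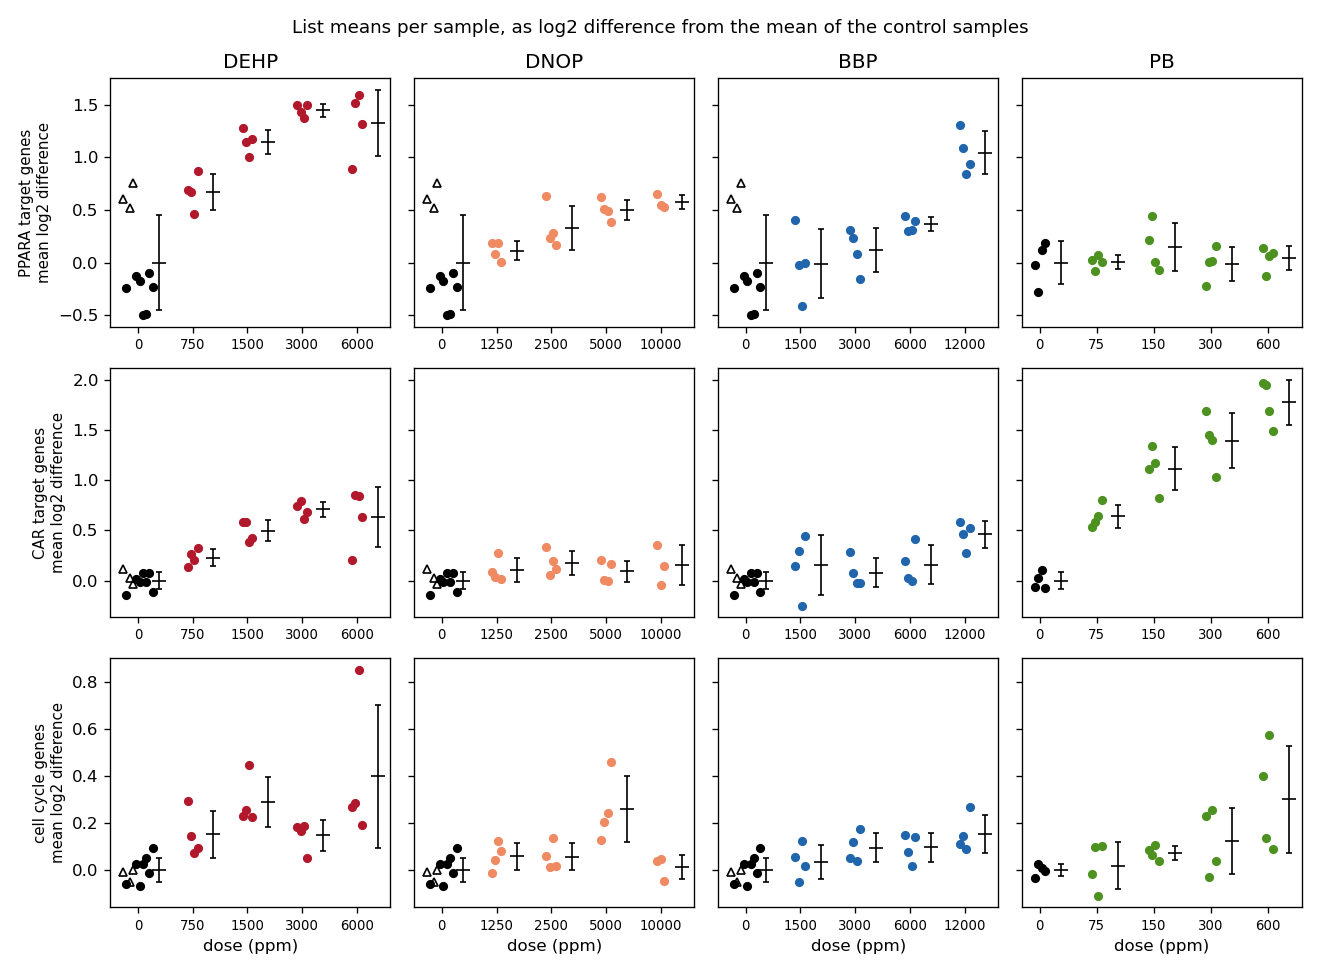
Mean log2 intensity over the tested PPARA, CAR and cell cycle lists in each sample, less the mean of its controls, against the dose in ppm of each compound; open triangles are the phthalate controls numbered 32, and lines with bars give the group mean ± SD. The PPARA mean was higher by 1.33 at 6000 ppm DEHP and 1.05 at 12000 ppm BBP and the CAR mean by 1.77 at 600 ppm phenobarbital, while the cell cycle median turned to −0.265 there and to −0.0339 at 12000 ppm BBP with each array centred on its median.

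DNOP raised few genes in the unweighted fit, and those it raised at 10000 ppm were mostly PPARA targets. There Cyp4a14 rose 20-fold (log2 change 4.32, SE 0.883, limma adjusted p = 0.012), Acot1 7.8-fold (adjusted p = 0.00838) and Ehhadh 5.64-fold (adjusted p = 0.012). The fatty acid hydroxylase gene Cyp4a12b rose 3.82-fold, the aldehyde dehydrogenase gene Aldh3a2 3.36-fold (adjusted p = 0.00117) and Retsat, which saturates retinol, 2.61-fold. With the controls numbered 32 left out, Cyp4a14, Acot1 and Ehhadh were 51.3, 15.3 and 8.43-fold higher. Pdk4 stood at 0.04 (adjusted p = 0.998), and at 0.64 without those controls (adjusted p = 0.999). At 5000 ppm Cyp4a14 rose 14.6-fold (adjusted p = 0.0159; 37.5-fold without those controls), Acot1 by 2.38 and Ehhadh by 2.0, and at 2500 ppm Cyp4a14 stood at 2.61 (adjusted p = 0.183).

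Of the 55 PPARA targets 0, 1, 7 and 5 rose at the 4 DNOP doses, where limma gave 456, 979, 957 and 605 of all genes at an unadjusted p under 0.05. With the adjustment over the list alone, 0, 8, 17 and 20 rose. The list medians were 0.08, 0.19, 0.36 and 0.39 (camera adjusted p = 0.00557, 3.97e-08, 1.27e-18 and 1.49e-24). The calls at 5000 and 10000 ppm held with an estimated correlation, and those at the 2 lower doses were lost with adjusted p = 0.843 and 0.577 with an estimated correlation. The list mean was 0.50 above the controls at 5000 ppm (two-sided exact permutation p = 0.0619) and 0.58 at 10000 ppm (interval 0.255 to 0.897; exact p = 0.0734), neither past the test. Without the controls numbered 32, 3, 9, 17 and 17 targets rose, and the calls had adjusted p = 0.0042, 0.00162, 2.40e-05 and 5.18e-07 with an estimated correlation. Without them Cyp4a14 was 15.7-fold higher at 2500 ppm and Acot1 4.51-fold higher at the lowest dose. Those controls were left out for their high PPARA targets, so calls gained without them are no separate support.

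In the fit of all samples no other list had a call that held with an estimated correlation at 10000 ppm DNOP. The cell cycle median was 0.00245 (camera adjusted p = 0.632) and turned negative, down to −0.13, with each other scaling. At 5000 ppm it was 0.24 and turned to −0.02 with each array centred on its median (adjusted p = 8.76e-12, held with an estimated correlation). Without the controls numbered 32 the median was 0.23 (camera adjusted p = 4.16e-09, lost with adjusted p = 0.132 with an estimated correlation). The list mean at 5000 ppm was 0.26 above the controls (two-sided exact permutation p = 0.000999, adjusted 0.005). There 9 of 47 members rose adjusted over the list alone and 0 over all genes (limma unadjusted p under 0.05 for 957 of all genes). The CAR list at 10000 ppm had a median of 0.12 (adjusted p = 0.0242, lost with adjusted p = 0.373 with an estimated correlation), with Cyp2b10 at 0.0185, and was not called at 0.0196 without replicate 1. The CAR mean was 0.15 above the controls (exact p = 0.0699), and at 2500 ppm it was 0.18 above them (exact p = 0.00699, adjusted 0.0262). Cholesterol synthesis had 0.40 (adjusted p = 3.14e-06, lost with adjusted p = 0.239 with an estimated correlation), and 0.07 without the controls numbered 32. Coagulation and complement had −0.16 (adjusted p = 1.74e-05, lost with adjusted p = 0.0691 with an estimated correlation, and called without those controls with adjusted p = 0.0468 with an estimated correlation).

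Over all genes DNOP changed 0, 27 (6 higher, 21 lower), 24 (17 and 7) and 7 (7 and 0), where limma gave 456, 979, 957 and 605 at an unadjusted p under 0.05. Of these, 2 of the 27 and 7 of the 24 were called in the same direction at 10000 ppm. The remaining gene of the 7, named after its value was seen, has the array ID LOC100044221. The counts were 3, 58, 80 and 31 without the controls numbered 32, and array quality weights gave 219, 123 and 301 at the 3 higher doses. Leaving out 1 sample gave 1 and 2 genes at the lowest dose (DNOP replicate 1, control replicate 1) and, at 10000 ppm, 2 without DNOP replicate 1 or 4 and 14 and 13 without control replicates 1 and 3. At 2500 ppm it gave 2, 7, 1 and 12 without DNOP replicates 1 to 4 and 57, 14, 13, 10, 10 and 11 without control replicates 1, 2, 4, 7, 9 and 10. At 5000 ppm it gave 2, 2, 7 and 15 without DNOP replicates 1 to 4 and 42 and 15 without control replicates 1 and 5. The calls of Cyp4a14 (4.14, 4.26 and 4.55) and Acot1 (2.93, 2.93 and 3.03) at 10000 ppm ended without replicate 1, 2 or 4. That of Ehhadh ended without replicate 1 or 4 (1.81 and 2.78) or with samples of 1 number averaged (2.57), and all 3 ended in a fit of the DNOP groups and their controls alone (4.33, 2.97 and 2.5).

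DEHP and BBP, which differ in their ester chains, were compared at the 3 doses both were given, and PPARA targets were higher with DEHP at each. At 1500 ppm Cyp4a14 was 39.1-fold higher with DEHP (log2 difference 5.29, SE 0.932, limma adjusted p = 0.000167). Cyp4a31 was 20.4-fold, Ehhadh 19.3-fold, Acot1 15.5-fold and the keratin gene Krt23 14.2-fold higher. At 3000 ppm Acot3 was 44.1-fold higher (adjusted p = 8.63e-12), Krt23 26.3-fold, Cyp4a14 16.6-fold, Cyp4a31 16.3-fold and Acot1 14.4-fold. At 6000 ppm Acot3 was 36.1-fold, Krt23 14.8-fold, Ly6d 9.84-fold, Cyp4a31 8.82-fold and Pdk4 7.45-fold higher. The folds of genes dim with BBP varied over the scalings, with 11.2 to 44.1 and 10.1 to 42 for Acot3 at 3000 and 6000 ppm, 5.37 to 14.3, 8.93 to 27.7 and 5.31 to 17.3 for Krt23 at the 3 doses, and 3.62 to 11.5 for Ly6d. No difference was detected at 6000 ppm for Cyp4a14 (0.94, SE 0.932, interval −0.923 to 2.8, adjusted p = 0.905). The samples of the 2 groups did not overlap, with 13.2 ± 0.124 for DEHP and 12.3 ± 0.459 for BBP (SD, n = 4 each), and the SE is pooled over all groups, among them the phthalate controls with an SD of 2.62.

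Of the 55 PPARA targets 25, 34 and 24 were higher with DEHP than with BBP and none was lower. With the adjustment over the list alone, 40, 43 and 33 were higher. The list medians were 0.89, 1.03 and 0.77 (camera adjusted p = 1.30e-60, 1.79e-55 and 6.02e-42, held with an estimated correlation). The list mean was higher by 1.16 (interval 0.815 to 1.5), 1.33 (0.986 to 1.68) and 0.97 (0.622 to 1.31). Each had a two-sided exact permutation p = 0.0286, the smallest that 4 against 4 samples can give (adjusted 0.0553).

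CAR targets were also higher with DEHP, 3, 5 and 6 of 39 (3, 11 and 11 adjusted over the list alone). Cyp3a11 was higher by 2.34, 3.46 and 2.60, Abcc3 by 1.42 and 2.06 at 1500 and 3000 ppm, and Cyp2b9 by 2.97 and 2.48 at 3000 and 6000 ppm. Cyp2b10 and the epoxide hydrolase gene Ephx1 were higher by 1.93 and 1.44 at 6000 ppm. Cyp2b10 was detected in none of the samples of 6000 ppm BBP, and its difference ran from 0.32 to 2.26 over the scalings. That of Cyp2b9, detected in none and 1 of the BBP samples, ran from 0.85 to 2.97 and from 1.11 to 2.82. The list medians were 0.26, 0.47 and 0.30 (camera adjusted p = 0.000115, 3.99e-09 and 6.65e-08), and the first was lost with adjusted p = 0.115 with an estimated correlation. The list mean was higher by 0.34 (interval 0.0979 to 0.574), 0.63 (0.393 to 0.869) and 0.48 (0.239 to 0.715), with two-sided exact permutation p = 0.0857, 0.0286 and 0.0571 (adjusted 0.126, 0.0553 and 0.104, none past the test).

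Coagulation and complement genes were lower with DEHP than with BBP, 5, 13 and 7 of 32 (15, 20 and 14 adjusted over the list alone, with 1 higher at 6000 ppm). Their medians of −0.36, −0.37 and −0.38 held (adjusted p = 0.000162, 5.36e-05 and 0.000154 with an estimated correlation). Of the 47 cell cycle genes 3, 1 and 7 were higher (4, 1 and 14 adjusted over the list alone), with list medians of 0.19, 0.05 and 0.27, of which the second turned to −0.16 with each array centred on its median. The camera adjusted p was 8.54e-09, lost with adjusted p = 0.0704 with an estimated correlation, then 0.301, and 2.20e-09, which held. Means of the list were higher by 0.25, 0.05 and 0.30 (two-sided exact permutation p = 0.0286, 0.229 and 0.0286; adjusted 0.0553, 0.275 and 0.0553), and none of these differences passed the adjustment. At 6000 ppm DEHP replicate 3 stood apart from the other DEHP samples, as given above. Prc1 was higher by 1.17 at 1500 ppm and 1.12 at 6000 ppm, and Spc25 by 1.16 and 1.27 at 1500 and 3000 ppm. Serpina12 was lower with DEHP at each dose (−1.33, −2.96 and −3.75). Also lower were Dnaic1 (−1.95), Mmd2 (−1.83), Lrtm1 (−1.82) and Irf5 (−1.31) at 1500 ppm, and Moxd1 (−3.70), the trefoil factor gene Tff3 (−3.27), Rnase2a (−2.95) and the ferritin receptor gene Scara5 (−2.35) at 3000 ppm. At 6000 ppm Saa4 (−1.78), Gm4956 (−1.67), the anion transporter gene Slc22a7 (−1.25) and Gna14 (−1.17) were lower.

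Over all genes DEHP and BBP differed in 193 genes at 1500 ppm (128 higher with DEHP, 65 lower), 465 at 3000 ppm (237 and 228) and 254 at 6000 ppm (189 and 65). The count of 193 was 127 without BBP replicate 3 and 114 and 126 without DEHP replicates 1 and 4, and that of 254 was 161 and 165 without BBP replicates 2 and 4 and 111 and 153 without DEHP replicates 2 and 3. Centring each array gave 98 and 160 for these doses, and array quality weights gave 401, 1147 and 499 genes. DNOP was given at other doses than DEHP and BBP, so its values stand beside theirs without a test. Cyp4a14 was 20-fold higher at 10000 ppm DNOP, 29.6-fold at 6000 ppm DEHP and 35.6-fold at 12000 ppm BBP. Ehhadh was 5.64, 23.2 and 20.1-fold higher, and the PPARA list medians were 0.39, 1.05 and 0.81.

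**Figure D3:**
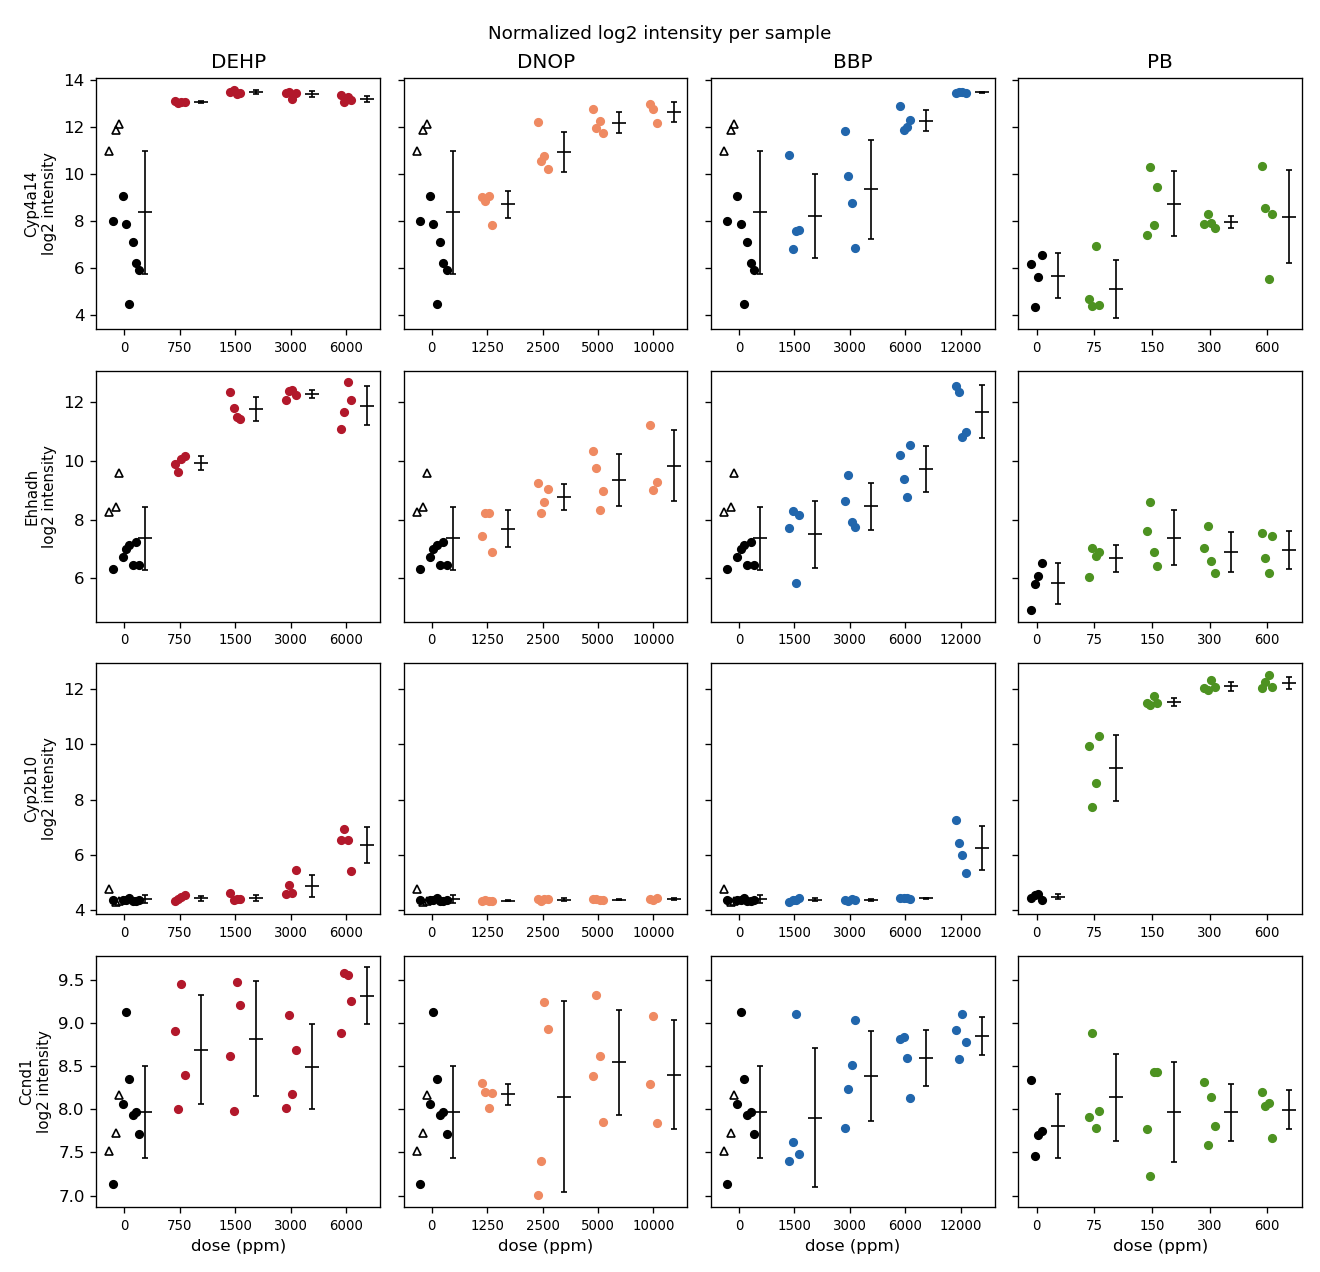
Log2 intensity of Cyp4a14, Ehhadh, Cyp2b10 and Ccnd1 in each sample against the dose in ppm of each compound, with lines and bars for the group mean ± SD; open triangles are the phthalate controls numbered 32. Cyp2b10 stood 46.1 to 212-fold above its controls at 600 ppm phenobarbital and 1.25 to 3.9-fold at 6000 ppm DEHP over the scalings, and Ehhadh was 23.2-fold higher at 6000 ppm DEHP.

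Phenobarbital raised CAR targets at every dose. At 600 ppm Cyp2b10, the marker gene of CAR, rose 212-fold (log2 change 7.73, SE 0.279, limma adjusted p = 1.34e-32), with 12.2 ± 0.218 against 4.49 ± 0.0996 (SD, n = 4 each). Its fold is set by the background and the offset, since it was detected in none of the 4 controls, and it ran from 46.1 to 212 over the scalings. Cyp3a11, detected in all 4 controls, rose 27.5-fold (22.3 to 31 over the scalings), and Cyp2c55, detected in 2, rose 147-fold (39.7 to 147). Also detected in none of the controls were Cyp2b23 (15.4 to 71.3-fold), the glutathione transferase genes Gsta1 (2.61 to 10.2) and Gstm3 (1.13 to 2.56) and the lipase-related gene Pnliprp1 (2.05 to 10.2), all higher at 600 ppm. Over the scalings Cyp2b10 was 5.7 to 25.1, 29.2 to 133 and 42.6 to 196-fold higher at 75, 150 and 300 ppm, and Cyp2c55 4.67 to 15.9, 17.2 to 61.8 and 30.5 to 112-fold.

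Of 39 CAR targets 8, 14, 23 and 28 rose at the phenobarbital doses and none fell. Adjusted over the list alone, 8, 16, 26 and 34 rose. The list medians were 0.44, 0.55, 0.99 and 1.43 (camera adjusted p = 4.51e-07, 5.45e-16, 2.57e-29 and 3.38e-44). The call at 75 ppm was lost with adjusted p = 0.113 with an estimated correlation and the other 3 held. The list mean was higher by 0.64, 1.11, 1.39 and 1.77, each with a two-sided exact permutation p = 0.0286, the smallest possible (adjusted 0.0553). From 75 ppm upward 7 targets passed, 7 from 150, 9 from 300 and 5 at 600 ppm. Against the phthalate controls 7, 9, 18 and 25 targets rose.

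No rise of PPARA targets as a group was detected with phenobarbital. At 600 ppm 0 of 55 rose and 2 fell, the glycerol genes Gpd1 (−0.81) and Aqp3 (−0.56), and 0 passed adjusted over the list alone (limma unadjusted p under 0.05 for 2774 of all genes). The list median was 0.00382 (camera adjusted p = 0.92) and the list mean differed by 0.04 (interval −0.302 to 0.388; two-sided exact permutation p = 0.714). This median turned to −0.0624 without the 2 dimmest phenobarbital controls, to −0.0336 with array quality weights and to −0.265 against the phthalate controls, a list lower there with camera adjusted p = 5.08e-07. At 75, 150 and 300 ppm 0, 2 and 1 targets rose and 0, 2 and 3 fell (limma unadjusted p under 0.05 for 2484, 3106 and 2593 of all genes). The list medians there were −0.00747, 0.03 and −0.02 (camera adjusted p = 0.99, 0.681 and 0.899), of which the first turned to 0.00368 with the deposited matrix and the last to 0.06 with each array centred on its median. Cyp4a14 rose 8.55-fold at 150 ppm (log2 change 3.10, adjusted p = 0.0278), where Ehhadh stood at 1.58 (adjusted p = 0.0518). At 600 ppm Cyp4a14 stood at 2.53 (adjusted p = 0.0833), and the change passed without replicate 3 of 600 ppm (3.38), with each array centred on its median (2.39), with a replicate block (2.53) and with array quality weights (2.63). It was 1.84 without replicate 1 (adjusted p = 0.255) and −0.15 against the phthalate controls.

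Some cell cycle genes rose at 600 ppm phenobarbital, 7 of 47, and 1 fell (11 and 1 adjusted over the list alone). The helicase gene Mcm6 rose by 1.44, Prc1 by 1.32, Cdc20 by 1.23, Cdca3 by 1.06 and Top2a by 0.55. The list median of 0.24 turned to −0.27 with each array centred on its median (camera adjusted p = 1.74e-05, lost with adjusted p = 0.496 with an estimated correlation). Per sample the list mean was 0.30 above the controls (two-sided exact permutation p = 0.0286, the smallest possible; adjusted 0.0553). Top2a was detected in none of the 4 controls and Cdc20 in 1, and over the scalings they ran from −0.27 to 0.55 and from 0.16 to 1.23. The call of Top2a ended without replicate 3 (0.39) and with that centring (−0.27). Among called genes whose groups did not overlap, the largest falls were those of the inositol kinase gene Ip6k2 (−2.63), Mospd3 (−2.19) and Dnaic1 (−2.09). In that set they were followed by the asialoglycoprotein receptor gene Asgr2 (−1.91) and the cholesterol hydroxylase gene Cyp46a1 (−1.89). Dnaic1 had a mean log2 intensity of 6.75 at 600 ppm, 8.83 in the phenobarbital controls and 7.74 in the phthalate controls. The protein disulfide isomerase genes Pdia6 (1.45), Pdia4 (1.12) and Pdia3 (0.86) and Edem1 (0.80) rose among 24 unfolded protein genes (median 0.20, camera adjusted p = 0.364), and none of these 4 was among the calls against the phthalate controls. The fasting genes Irs2 (−1.45) and Ppargc1a (−1.27) fell, and of 4 AHR targets Cyp1a2 rose by 1.46. Against the phthalate controls 0 of 17 fasting genes were called, and 1 of the 4 AHR targets was higher.

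Over all genes phenobarbital changed 733 genes at 75 ppm (287 higher, 446 lower), 1311 at 150 ppm (539 and 772), 961 at 300 ppm (366 and 595) and 1126 at 600 ppm (490 and 636). Of the first 3 sets 385, 740 and 664 were called in the same direction at 600 ppm. Without the 2 dimmest phenobarbital controls the counts were 316, 490, 277 and 441, against the phthalate controls 301, 19, 83 and 227, and with each array centred on its median 82, 5119, 4445 and 5105. Leaving out 1 sample gave 443, 576, 436 and 614 without control replicate 1, 1262, 314, 1139 and 307 without replicates 1 to 4 of 75 ppm, 738 and 834 without replicates 2 and 3 of 150 ppm, 600 and 515 without replicates 1 and 2 of 300 ppm, and 721 and 713 without replicates 2 and 4 of 600 ppm.

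At their top doses DEHP, BBP and phenobarbital shared genes beyond the number independent lists would give. DEHP and BBP shared 141 genes higher and 120 lower, where independent lists would share 8.92 and 6.81 (one-sided Fisher's exact p = 1.33e-156 and 7.41e-134). Among these were 29 PPARA targets and 4 CAR targets that rose and 11 coagulation and complement genes that fell. DEHP and BBP have the same controls, so each was also set against a separate part of them, which left 104 or 64 shared genes higher and 66 or 45 lower. All 7 genes higher with DNOP were higher with DEHP (0.367 for independent lists, p = 1.06e-09; 25 and 0 with split controls) and with BBP (0.105, p = 1.52e-13; 0 and 18 with split controls), and 5 of them are PPARA targets.

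DEHP and phenobarbital, which have separate controls, shared 98 genes higher and 129 lower (25.7 and 26.4 for independent lists, one-sided Fisher's exact p = 2.74e-32 and 3.89e-56). Among the genes higher were 10 CAR targets and 6 cell cycle genes. BBP and phenobarbital shared 17 and 19 (7.36 and 9.21; exact p = 0.00111 and 0.00212), with 5 CAR targets higher. DNOP and phenobarbital shared 1 gene (0.303; exact p = 0.266). Across genes, which are not independent replicates, the correlation of log2 changes was 0.675 for DEHP and BBP, 0.581 for DEHP and DNOP and 0.502 for DNOP and BBP. Simulated data with shared controls and no shared effects gave 0.316, 0.281 and 0.286. With separate parts of the controls the data gave 0.461 and 0.435, 0.433 and 0.152, and 0.0653 and 0.318. For phenobarbital with DEHP, DNOP and BBP it was 0.35, 0.244 and 0.327.

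The phenobarbital controls were compared with the phthalate controls as the background between the parts of the study. PPARA targets were lower in the phenobarbital controls, 7 of 55 (14 adjusted over the list alone) with 1 higher. Among them were Cyp4a14 (−2.68, SE 0.81, limma adjusted p = 0.0385), Ehhadh (−1.55), the carnitine carrier gene Slc22a5 (−0.98) and Acadl (−0.68). The list median was −0.29 (camera adjusted p = 7.70e-06, lost with adjusted p = 0.533 with an estimated correlation). Without the controls numbered 32, 0 of the 55 were lower, 1 was higher and the median was −0.14 (limma called 585 of all genes in that fit, and 2147 had an unadjusted p under 0.05 in the fit of all samples). Higher in the phenobarbital controls were Rps23rg1 (1.53), the immune receptor gene Oscar (1.27), the ferrireductase gene Steap3 (1.26), Terb1 (1.06) and Spen (1.0). Lower were Cldnd1 (−1.21), the helix-loop-helix gene Id3 (−1.01), Eepd1 (−0.96), the splicing gene Hnrnpl (−0.89) and the purine synthesis gene Atic (−0.89). In all 528 genes differed (357 higher, 171 lower), and the count was 149 without phenobarbital control replicate 1, 36 without both dim controls and 4147 with each array centred on its median.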

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

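The tests of the 3 patterns weighed here were chosen after the results had been seen, while the search for samples far from the others of their group was fixed before the data were examined. That search found such a sample in 22 of 323 combinations of a group and a measure (6.81%), where chance gives about 1 in 20.

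Phthalate control replicates 1 to 3, numbered 32 in the labels, had PPARA targets higher by 0.894 and cholesterol synthesis genes at −1.21 (log2) against the 7 other phthalate controls, with Cyp4a14 at 11.67 against 6.97 and Sqle at −2.92. Other lists moved with them: female-biased genes stood at 0.607 (lowest of the 3 samples 6.127, highest of the others 5.77), unfolded protein genes at −0.52 (highest 7.699, lowest of the others 7.833), and, with samples that overlap, acute phase genes at −0.756 and neutrophil and red cell markers at −0.769 and −0.737. Array quality is argued against, since over 77 samples the deviation of the PPARA list mean from its group mean had a Spearman correlation of −0.083 with that of the percent of genes detected (permutation p = 0.471; Pearson −0.0919, permutation p = 0.426; −0.0893 and −0.102 without the 2 samples farthest from the median). Exposure to a phthalate alone or a swapped label is argued against by the cholesterol synthesis list at −1.21, which lies below all 12 phthalate dose groups (−0.316 to 0.253 against the same controls). Feeding state is a candidate explanation that stays open: the fasting list was higher by 0.299 and fatty acid synthesis stood at −0.522, with G6pc at 1.17, Pck1 at 0.73 and Igfbp1 at −0.202. The design names no biological difference between these controls and the others.

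Against the phthalate controls 886 genes were called with phenobarbital control replicates 1 and 2 alone, 27 with replicates 3 and 4, and 13 in both. The low signal of replicates 1 and 2 may account for the difference between the control groups. Replicates 3 and 4 showed a median of 0.239 of the shift, although the genes were chosen on the dim arrays, which lowers this ratio. A difference between the phenobarbital and phthalate parts of the study is argued against, since the dose groups of phenobarbital showed medians of 0.151, −0.111, −0.0453 and 0.00128 of the shift, the highest being 0.151. What made the arrays dim stays open, and no biological explanation was tested.

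Cell cycle genes were higher at 6000 ppm DEHP, most in replicate 3, whose list mean of 0.8517 above the controls stood far from 0.1932 to 0.2842 in the other samples. Quantile normalization is argued against as the whole cause, since the list median was 0.275 with each array centred on its median. A single sample is argued against as the whole cause of the list's shift, since the lowest median without any 1 sample was 0.224 (without replicate 3), although 8 of the 21 genes were then called. More immune cells could contribute and cannot be told apart from cycling hepatocytes: the highest median of the macrophage, lymphocyte and neutrophil marker lists was 0.231, for macrophages, and none passed its test. The exposure itself stays among the open explanations.

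In the percent of genes detected, DNOP 5000 ppm replicate 3 stood low at 41.75% (others 45.21 to 45.59) and phenobarbital 150 ppm replicate 1 at 43.55% (others 45.44 to 45.82). The cell cycle mean above the controls was far higher in DEHP 1500 ppm replicate 3, 0.4474 (others 0.2266 to 0.2558), and far lower in DEHP 3000 ppm replicate 4, 0.05227 (others 0.166 to 0.1881). Cyp4a14 stood at 6.949 in phenobarbital 75 ppm replicate 3 (others 4.385 to 4.708; log2 intensity, as in what follows). Fgf21 was high in DEHP 6000 ppm replicate 2 at 9.451 (others 7.852 to 8.087). Cyp2b10 was high in phthalate control replicate 1 at 4.766 (others 4.287 to 4.425), in lowest-dose DNOP replicate 2 at 4.367 (others 4.338 to 4.34) and in DEHP 1500 ppm replicate 1 at 4.61 (others 4.376 to 4.399). Cyp2c55 was high in phthalate control replicate 4 at 6.346 (others 4.478 to 5.064) and DEHP 3000 ppm replicate 1 at 6.91 (others 6.084 to 6.212), and low in phenobarbital 600 ppm replicate 4 at 11.64 (others 12.26 to 12.38). Cyp3a11 was low in DEHP 1500 ppm replicate 3 at 10.02 (others 12.37 to 12.82). Gstm3 was high in phthalate control replicate 2 at 4.574 (others 4.263 to 4.407) and lowest-dose DNOP replicate 1 at 4.68 (others 4.363 to 4.413). Ccnb1 was high in BBP 3000 ppm replicate 2 at 4.541 (others 4.355 to 4.37) and DEHP 6000 ppm replicate 3 at 6.279 (others 4.298 to 4.523), and Cdk1 in the latter sample at 5.479 (others 4.471 to 4.579). Ccnd1 was high in BBP 1500 ppm replicate 3 at 9.102 (others 7.405 to 7.622). Mcm5 was high in lowest-dose DNOP replicate 3 at 5.965 (others 5.428 to 5.491) and DEHP 1500 ppm replicate 3 at 6.299 (others 5.579 to 5.585).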

How the results depend on the processing

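The settings with neqc's background, with array quality weights, without the controls numbered 32, without the 2 dimmest phenobarbital controls, without the 4 arrays of lowest weight and against the phthalate controls were tests chosen after the data were seen, and the others were planned. The signal over background limits dim genes, whose changes shrink without background correction, and the 3 to 4 arrays per dose limit the counts. All 20 counts stayed within 1.5 times their value with neqc's background, without background correction, with the deposited matrix and with a trended robust prior, and 176 of 237 did so with 1 sample left out. Of the 12 list tests at the top doses, 12 kept their direction and side of the threshold with no block, a replicate block, averaged samples, the strict filter and the low-weight arrays left out; with 1 sample left out 134 did, 12 reversed and 1 weakened. Of panel genes with 1 sample left out, 644 were the same, 22 reversed, 5 were stronger and 15 weaker. The causes were not tested except where fewer samples or genes enter. A slide block and another probe per gene were not run, for want of slides and of further probes.

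Centring each array on its median gave 81 and 267 genes at 750 and 1500 ppm DEHP, 165 at 12000 ppm BBP, 82, 5119, 4445 and 5105 at the phenobarbital doses, 98 and 160 between DEHP and BBP at 1500 and 6000 ppm and 4147 between the controls. It reversed, at 600 ppm phenobarbital, Ccnb1 (−0.599), Cdk1 (−0.581), Top2a (−0.265) and the cell cycle median (−0.265), at 12000 ppm BBP Ccnb1 (−0.0426), Cdk1 (−0.102) and the cell cycle median (−0.0339), at 10000 ppm DNOP Cyp2b10 (−0.146), Top2a (−0.134) and the cell cycle median (−0.134), and at 6000 ppm DEHP Gstm3 (−0.367). At 10000 ppm DNOP, Pdk4 reversed with neqc's background (−0.205), no background correction (−0.061), the deposited matrix (−0.0662) and the replicate block (−0.0254), and the cell cycle median with the first 3 (−0.00123, −0.000368, −0.00203), with no filter (−0.0166), with weights (−0.0493) and without the controls numbered 32 (−0.0458).

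Array quality weights gave 1364 and 1966 genes at 1500 and 3000 ppm DEHP, 219, 123 and 301 at 2500, 5000 and 10000 ppm DNOP, 1, 1, 108 and 928 at the BBP doses, 401, 1147 and 499 between DEHP and BBP and 192 between the controls, and reversed Mcm5 at 10000 ppm DNOP (−0.081), Acot1 (−0.339) and the PPARA median (−0.0336) at 600 ppm phenobarbital. Without the low-weight arrays the counts were 41 and 13 at 2500 and 10000 ppm DNOP, 19 at 6000 ppm BBP, 239, 796, 581 and 734 for phenobarbital, 92 between DEHP and BBP at 1500 ppm and 181 between the controls. Without the controls numbered 32 they were 332 at 750 ppm DEHP, 3, 58, 80 and 31 for DNOP and 1, 6 and 28 at the 3 lower BBP doses, and Gstm3 reversed at 12000 ppm BBP (0.00786). Without the 2 dimmest phenobarbital controls they were 316, 490, 277 and 441 for phenobarbital and 36 between the controls, with Acot1 (−1.13) and the PPARA median (−0.0624) reversed at 600 ppm. Against the phthalate controls phenobarbital gave 301, 19, 83 and 227, and reversed at 600 ppm Acot1 (−0.917), Cyp4a14 (−0.147), Ehhadh (−0.372), Pdk4 (−0.612) and the PPARA median (−0.265).

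Averaging samples of 1 number gave 108, 317 and 617 at the 3 lower DEHP doses, 15 and 12 at 2500 and 5000 ppm DNOP, 3 and 185 at 6000 and 12000 ppm BBP, 286, 550, 415 and 590 for phenobarbital and 318 between the controls. A fit of the same compounds alone gave 49 and 4 at 2500 and 10000 ppm DNOP, 1 at 6000 ppm BBP, 156, 693, 393 and 572 for phenobarbital and 54 between the controls. No block gave 18 at 6000 ppm BBP. The strict filter gave 12 at 10000 ppm DNOP, 17 at 6000 ppm BBP, 625 at 300 ppm phenobarbital and 256 between the controls. No filter gave 13 at 2500 ppm DNOP and 836 between the controls, with the PPARA median at 600 ppm phenobarbital at −0.000605. Replicate numbers do not pair samples: 127 of 300 pairs of phthalate samples with the same number (42.3%) and 4 of 20 phenobarbital pairs (20%) correlated above 0.1, with means of 0.0481 and −0.049. A replicate block gave 41 at 2500 ppm DNOP and 22 at 6000 ppm BBP.

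With 1 sample left out the counts ranged over 78 to 333, 321 to 594, 597 to 1007 and 651 to 1159 for DEHP, 0 to 2, 1 to 57, 2 to 42 and 2 to 14 for DNOP, 0 to 0, 0 to 1, 1 to 29 and 150 to 376 for BBP (where limma gave 456, 399 and 436 genes at an unadjusted p under 0.05 for the counts of 0), 307 to 1262, 576 to 1388, 436 to 1019 and 614 to 1195 for phenobarbital, 114 to 208, 331 to 445 and 111 to 330 between DEHP and BBP, and 149 to 691 between the controls. Results that reversed or weakened ranged, at 10000 ppm DNOP, over −0.0286 to 0.0206 for the cell cycle list, 0.0196 to 0.183 for the CAR list, −0.103 to 0.235 for Pdk4, −0.269 to 0.0631 for Cyp2c55 and −0.0443 to 0.0928 for Top2a. The ranges were −0.0111 to 0.0249 for Gstm3 at 6000 ppm DEHP, −0.0231 to 0.14 for Mcm5 at 12000 ppm BBP, and at 600 ppm phenobarbital −0.0166 to 0.0889 for the PPARA list, −0.327 to 0.683 for Acot1 and −0.0365 to 0.294 for Pdk4.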

Other observations

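The test on samples of 1 number was written before its result was seen, and the lists and splits were planned; no other test is added here. At 6000 ppm DEHP single genes moved in lists whose own test did not pass: the lipogenic enzyme gene Me1 (1.79), the acyltransferase gene Gpam (1.29), Fads2 (1.11) and pyruvate kinase Pklr (−1.24) among 23 fatty acid synthesis genes (5 rose, 2 fell; median 0.07, camera adjusted p = 0.258), Cyp2c70 (−1.06), Hsd17b4 (0.98), the sterol exporter gene Abcg5 (0.62) and Cyp7b1 (−0.52) among 24 bile acid genes (3 and 3; median −0.10, adjusted p = 0.518), and Gstm4 (1.44), Srxn1 (1.42), Gstp1 (−1.11) and Pgd (0.75) among 29 NRF2 and glutathione genes (6 and 1; median 0.04, −0.06 with each array centred on its median, adjusted p = 0.258). Of 4 AHR targets Nfe2l2 rose by 0.55 (list adjusted p = 0.698), and among 24 unfolded protein and stress genes Calr (−1.25) and Hyou1 (−1.18) fell and Vldlr rose by 1.23 (median −0.23, adjusted p = 0.149). Of 17 fasting genes and 16 clock genes none passed (limma; 2348 of all genes at an unadjusted p under 0.05), with list adjusted p of 0.539 and 0.651; the fasting median of 0.00315 differs in sign from its mean of −0.08 and from its test, and turned to −0.03 or below with the other scalings.

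Markers of other liver cells moved little at 6000 ppm DEHP. Medians were 0.23 for Kupffer cells (adjusted p = 0.277), −0.05 for lymphocytes (0.3), −0.01 for neutrophils (0.856), 0.05 for endothelial cells (0.999), 0.02 for stellate cells (0.856; mean −0.01, and −0.07 with each array centred on its median), −0.17 for cholangiocytes (0.258), −0.02 for acinar cells (0.539) and 0.22 for adipocytes (0.1; −0.02 with that centring), where 3 of the 4 tested adipocyte genes stand in another list. Members past the test were Stab2, Dcn, Ecm1 and the elastase gene Cela1, all lower, and Pnliprp1 and Cidec, higher. At lower doses the Kupffer list was lower at 1500 ppm (median −0.45, camera adjusted p = 0.003, lost with adjusted p = 0.306 with an estimated correlation), and it was lower with DEHP than with BBP at that dose (−0.77, 1.45e-08; lost with adjusted p = 0.0669 with an estimated correlation). The red cell list was lower at 1500 and 3000 ppm (−0.47 and −0.53; adjusted p = 0.0164 and 0.0132, lost with adjusted p = 0.238 and 0.191 with an estimated correlation) and, between DEHP and BBP, at 3000 ppm (−0.76, with Hba-a1 at −1.61; adjusted p = 0.00119, lost with adjusted p = 0.0775 with an estimated correlation).

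At 12000 ppm BBP the remaining lists gave camera adjusted p of 0.942 for bile acids, 0.0335 for NRF2 and glutathione (median 0.15; lost with adjusted p = 0.153 with an estimated correlation), 0.567 for AHR targets, 0.44 for amino acids, 0.942 for fasting, 0.11 for p53 targets, 0.0392 for unfolded protein genes (median −0.16; lost with adjusted p = 0.397 with an estimated correlation), 0.0809 for the clock and at least 0.196 for each cell type. At 10000 ppm DNOP calls that were lost with an estimated correlation were those of p53 targets (median 0.17, adjusted p = 0.0304, lost with 0.0619), female-biased genes (0.15, turned to −0.00432 with each array centred on its median; 0.011, lost with 0.0909), amino acid genes (−0.08; 0.0325, lost with 0.239), lymphocytes (−0.23; 0.00617, lost with 0.0574) and red cells (−0.34; 0.0222, lost with 0.239), of which the female-biased, lymphocyte and red cell lists had 0.0206, 0.0206 and 0.034 with an estimated correlation without the controls numbered 32; acute phase genes had 0.506, fatty acid synthesis 0.0952, AHR targets 0.112, bile acids 0.649, Kupffer cells and cholangiocytes 0.24, endothelial cells 0.179, stellate cells 0.384, adipocytes 0.69, acinar cells 0.732, and NRF2, fasting, unfolded protein, male-biased, clock and neutrophil genes 0.903. In this comparison the median and mean differed in sign for bile acids (0.01 and −0.03) and for NRF2 (0.07 and −0.04).

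At 600 ppm phenobarbital cell type markers past the test were the macrophage gene Adgre1 (1.59), the endothelial gene Dnase1l3 (−1.11), the stellate genes Lrat, Ngfr and Dcn, all lower, and among acinar genes Pnliprp1 (3.36) and the elastase genes Cela2a, Cela1 and Cela3b, all lower; the acinar median of −0.16 and its mean of 0.15 differ in sign. Of 16 p53 targets Polk (0.76), Fas (0.73) and Zmat3 (0.70) rose, and of 16 clock genes Npas2 rose and Hlf fell. Against the phthalate controls 0 Kupffer, endothelial and stellate markers, p53 targets and clock genes were called at that dose. Of the acinar genes 1 was higher there and 0 were lower. The camera adjusted p was 0.92 for cholesterol synthesis, bile acids, coagulation, acinar cells and red cells, 0.77 for the acute phase and the clock, 0.361 for fatty acid synthesis, 0.505 for NRF2, amino acids and both sex-biased lists, 0.3 for p53 targets, 0.222 for AHR targets, fasting, Kupffer and stellate cells, 0.248 for endothelial cells, 0.676 for lymphocytes, 0.621 for neutrophils, 0.715 for cholangiocytes and 0.745 for adipocytes. Coagulation had a median of −0.03 and a mean of 0.00973, and bile acids a median of 0.04 and a mean of −0.00887.

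Samples that share a number within the phenobarbital dose groups might share PPARA target levels through a shared feeding state or cage. The mean difference within numbers was 0.143 (log2) against 0.176 over all pairings, and 19 of the 81 possible pairings gave differences as small (share 0.235). The plan took a share of 0.05 or more as evidence against this. That bound was wrong, since a share above it does not show that samples of 1 number were no closer and the difference lies on the side a shared state needs, so this stays open. Over all lists, cholesterol synthesis, fatty acid synthesis and NRF2 genes were closest under the real pairing of 81 (exact p = 0.0123, adjusted 0.107), and none passed the adjustment.

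Other splits of the samples of 2 groups were fitted without the other groups. Chance was excluded where 1 split, the real one, gave as many genes: at the DEHP doses (63, 309, 991 and 768 genes; highest other split 30, 250, 1 and 11 of 100), at 2500 ppm DNOP (20; 6), at 12000 ppm BBP (239; 51), at 150, 300 and 600 ppm phenobarbital (858, 494 and 373; 1, 0 and 0 of 35), between DEHP and BBP (34, 852 and 64; 1, 0 and 0 of 35) and between the controls (115; 1). At the lowest DNOP dose, at 10000 ppm DNOP and at 1500, 3000 and 6000 ppm BBP the real split gave 0 genes, so every split, 100 of 100, gave as many, and the count bears neither on chance nor on the genes called in the fit of all samples (highest other 85, 4, 128, 10 and 47). At 5000 ppm DNOP 3 of 100 splits gave the real split's 2 genes or more, a share also under the 0.05 set before. At 75 ppm phenobarbital the real split of 35 gave 1 gene and the highest other 0. The 733 genes of the limma fit of all samples rest on a spread estimated over all groups. With these 2 groups alone nearly all of them were lost. In a fit of the phenobarbital groups and their controls the count was 156. The limma fit of all samples had 456 and 605 genes at an unadjusted p under 0.05 for these DNOP doses of 0 genes and 399, 436 and 989 for BBP. The split with 144 genes at 5000 ppm DNOP, against 2 in the real one, points to a structure among the samples.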
